A study of Mus musculus with 12 samples.

How the data were processed

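The series held 12 RNA-seq libraries of medullary thymic epithelial cells (mTEC), 3 from wild-type and 3 from Insm1-mutant CD1 mice at embryonic day 18.5 (E18.5) and as many from each genotype in adults. Per the labels, an E18.5 library came from a pool of 2 to 3 thymi and an adult library from 1 thymus. Cells were pulled down, per the labels, with beads carrying the lectin UEA1, and libraries were made from total RNA with a directional kit. Reads were mapped to the mouse build GRCm38 with STAR, handled with SAMtools and counted with HTSeq, per the submitters' processing notes, which gave no versions. The strand setting of the counting was not given.

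The deposited tables gave whole-number counts and FPKM for 25030 genes, the same identifiers at both stages, and the counts were the unit tested. The deposited FPKM equalled the counts scaled by the library total and by 1 whole gene length for 20040 of 20040 genes with reads in 2 or more libraries (tolerance 1e-06), so for these the FPKM carried no information beyond the counts, and they served in alternatives only. Symbols and GRCm38 positions were found for 24681 identifiers, and 349 without a match were kept under their identifiers. The matched set included 21382 protein-coding genes and 2675 long intergenic noncoding RNAs. Genes of the mitochondrial genome had 0 counts in all libraries of the deposited tables, so the mitochondrial share of the reads could not be given.

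Reads counted in genes were 23586733, 13124371 and 15775033 in wild-type replicates 1, 2 and 3 at E18.5, and 15406452, 14149759 and 14592398 in the mutants. Adult totals were 14463165, 15713948 and 16192231 in wild-type and 13694330, 16458417 and 15165960 in mutant replicates. No library was left out. Replicates of a group differed by more than read sampling, with chi-square per degree of freedom of 8.86 to 45.3 between pairs and correlations of log2 CPM of 0.991 to 0.996.

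Each comparison was tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, filterByExpr) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p below 0.05 were counted as changed. The 5 comparisons were mutant against wild-type at E18.5, the same in adults, the interaction of genotype and stage, adult against E18.5 wild-type, and an additive fit of genotype over both stages that was added after the values had been seen. CPM are TMM-scaled within the comparison unless called unscaled, and are given as mean ± SD of 3 libraries. Standard errors (SE) of log2 fold changes were the change over the root of its F statistic. Stage could not be separated from table, collection, pooling or sex makeup, so that comparison is descriptive.

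Alternatives were DESeq2 1.42.0 (Wald test), limma 3.58.1 voom with sample quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the authors' FPKM, DESeq2 size factors, total counts, no filter, CPM of 1 or more in 3 libraries, an absolute log2 fold change of 1 or more, 1 fit of all 12 libraries, replicate number as a block, and each library left out in turn. A covariate for the share of Y-linked reads, the omission of genes within 20 Mb of Insm1, the neuroendocrine list without Insm1 and differences within adult pairs were added after the values had been seen. The filter was rerun for each left-out library, so the tested members of a list could differ from those with all libraries. Figures were drawn with matplotlib 3.10.9.

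Gene lists were written from general knowledge and not checked against a database. They were 30: neuroendocrine, peptide hormone and neuropeptide, tuft, microfold, enterocyte and hepatocyte, goblet and secretory, pancreatic acinar, keratinocyte, ciliated, ionocyte, skeletal muscle, antigens commonly cited as Aire-dependent and as Aire-independent, mature mTEC, immature mTEC, cortical thymic epithelial (cTEC), epithelial, thymocyte, macrophage and dendritic, B cell, fibroblast and pericyte, endothelial, erythroid, parathyroid and thyroid, adipocyte, cell cycle, interferon response, dissociation stress, mitochondrial and sex-linked genes. Lists with 5 or more tested members were compared with all other genes by camera (limma; preset correlation 0.01), with camera at an estimated correlation beside it. The values of fry stand beside these but answer another question, whether a list differs from no change rather than from the other genes. All p were adjusted over the lists of a comparison. The sex-linked list served only as a check of the libraries. Names absent from the tables were Irag2, Sgne1, Amy2b, Loricrin, Flg, Dnai1, Dnai2, Spt1, Tp53aip1, Ighm, Ighd, Ahsp, Mx2, mt-Rnr1 and mt-Rnr2. The comparisons, tests, lists and naming rule were set before the data were examined.

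By the naming rule, Insm1, Aire and Fezf2 were given in each genotype comparison whatever their values. Up to 10 genes with the largest rise and 10 with the largest fall were added if their adjusted p was below 0.05, their average log2 CPM was 1 or more and their CPM did not overlap between genotypes, without predicted genes or receptor segments. Up to 4 passing members of each list were named in order of p, or, where none passed, up to 2 with the lowest p as values only. The interaction and stage comparisons took the 5 largest changes in each direction. Genes outside the rule are said to have been chosen after their values were seen.

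Replicate numbers were compared across genotypes by the correlation of each library's deviations from its group mean. In adults the 3 same-number correlations were 0.253, 0.141 and 0.150, so the numbers were treated as pairing the adult samples in the alternative with a block, although the labels name no shared animal or litter.

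The procedure was run on simulated counts with known changes. Of genes moved by a log2 fold change of 1, the share recovered was 73.5% at E18.5, 62.2% in adults, 34.3% for the interaction, 83.7% for stage and 72.2% for the additive fit, with 21, 12, 6, 10 and 10 false calls. At a log2 fold change of 2 the shares recovered were 97%, 92%, 73%, 93.9% and 95%. In adults 98 genes moved by 1 and 100 moved by 2 were tested, far more than edgeR called for genotype in the real libraries. With fewer changed genes the Benjamini-Hochberg threshold is stricter, so these shares may overstate what the real comparisons could detect. In the real adult libraries Insm1, at -2.06, had an edgeR adjusted p of 0.593 and was not called. A list shifted by -0.5 was recovered in all 5 comparisons, with 2 unshifted lists called in the interaction and 0 in the others. Genes were drawn independently of each other, so the simulation does not show how often camera calls lists of correlated genes. In the real libraries regrouped regardless of genotype, camera with the preset correlation called a median of 8 lists at E18.5 and 11 in adults. Each of these regroupings was an uneven mix of the genotypes. Part of any genotype effect thus remained in it, and the medians are not rates of false calls.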

Results

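mTEC express, at low level, genes that are otherwise confined to single tissues, and so show developing T cells a sample of the body's own proteins. Insm1 encodes a zinc-finger transcription factor of neuroendocrine cells, and the series asked what its loss does to the transcripts of mTEC. RNA was sequenced from 3 wild-type and 3 Insm1-mutant libraries at E18.5 (pools of 2 to 3 thymi) and from 3 of each in adults (single thymi). Libraries held 13124371 to 23586733 counted reads at E18.5 and 13694330 to 16458417 in adults. The name mTEC is that of the labels, and the preparations also held transcripts of other cells. Mean log2 CPM in wild-type E18.5 libraries was 8.90 for cTEC, 5.10 for mature mTEC and 1.77 for macrophage and dendritic cell genes. In wild-type adults it was 8.38 for endothelial, 6.41 for epithelial, 6.35 for mature mTEC and 4.14 for macrophage and dendritic cell genes. Such means do not give shares of cells. In every mutant library Insm1 (ENSMUSG00000068154, chromosome 2, 146221921 to 146225020, GRCm38) lay below every wild-type library of its stage. At E18.5 it had 457, 166 and 196 reads in wild-type and 31, 21 and 19 in mutant replicates. In adults it had 408, 251 and 260 against 73, 99 and 50. Reads from the gene thus remained in all mutants, and the labels do not describe the allele.

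At E18.5 the loss of Insm1 came with few single-gene changes. Insm1 fell from 14.9 ± 4.02 to 1.60 ± 0.367 CPM (log2 fold change -3.22 ± 0.27 SE, edgeR adjusted p 0.00507). Miat, a long noncoding RNA (ENSMUSG00000097767, chromosome 5, 112213228 to 112229395), fell from 5.74 ± 0.731 to 0.524 ± 0.160 CPM (-3.44 ± 0.32, adjusted p 0.00639). The interferon-induced Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) fell from 64.3 ± 4.21 to 37.9 ± 1.44 CPM (-0.76 ± 0.09, 0.0255). The sodium, potassium and calcium exchanger gene Slc24a3 (ENSMUSG00000063873, chromosome 2, 145167754 to 145642166) rose from 10.2 ± 1.15 to 27.2 ± 2.90 CPM (1.42 ± 0.14, 0.00965). Rin2, which encodes a Ras and Rab interactor (ENSMUSG00000001768, chromosome 2, 145675215 to 145887616), rose from 65.4 ± 7.65 to 122 ± 7.0 CPM (0.90 ± 0.10, 0.0212). Both genes that rose are neighbours of Insm1, 579755 bp and 334305 bp from it. These were all 5 genes that changed of 14497 tested (edgeR; 54 by DESeq2 and 30 by voom). An unadjusted p below 0.05 was found for 542 genes where chance alone would give 725.

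Leaving out single E18.5 libraries ended 4 of these 5 calls at least once. Insm1 kept an edgeR adjusted p of 0.0434 or less. Miat lost its call without wild-type 1 (0.0650) or mutant 3 (0.0635), and Slc24a3 without wild-type 1 (0.0741), mutant 2 (0.0912) or mutant 3 (0.0705). Rin2 lost it without wild-type 1 (0.0741), wild-type 3 (0.0709), mutant 2 (0.158) or mutant 3 (0.102). Ifi44 lost it without wild-type 1 (0.0741), wild-type 3 (0.104), mutant 1 (0.0977), mutant 2 (0.184) or mutant 3 (0.131). The count of changed genes was 1 without wild-type 1 or mutant 3, 2 without mutant 2, 3 without wild-type 3 and 9 without wild-type 2.

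Aire and Fezf2 encode the transcriptional regulators through which mTEC switch on much of their tissue-restricted repertoire. Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610) stood at 98.4 ± 14.4 CPM in wild-type and 55.4 ± 6.17 CPM in mutant E18.5 mTEC, without overlap. It missed the threshold in edgeR (-0.83 ± 0.12, adjusted p 0.0992) and passed it in DESeq2 (1.05e-05) and voom (0.0384). Fezf2 (ENSMUSG00000021743, chromosome 14, 12342094 to 12348189) stood at 17.6 ± 3.05 and 12.7 ± 2.29 CPM (-0.47 ± 0.18, edgeR adjusted p 1.0). At 8.01% of genes, 1161, the CPM of the genotypes did not overlap, against 10% by chance for 3 libraries against 3.

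**Figure D1:**
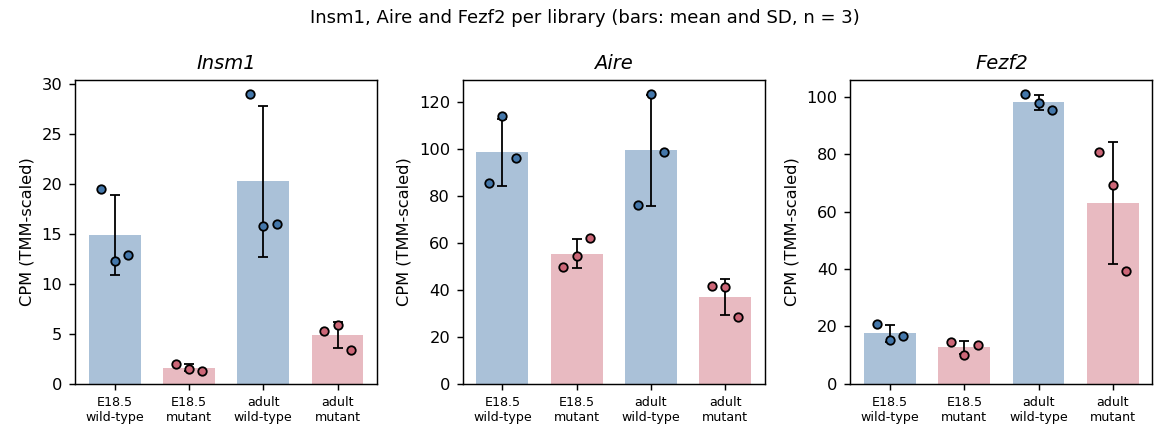
CPM of Insm1, Aire and Fezf2 in each library (points) of wild-type and mutant mTEC at E18.5 and in adults. The points of the genotypes do not overlap for any of the 3 genes at either stage, and mutant Insm1 averaged 1.60 CPM at E18.5 and 4.85 CPM in adults.

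Interferon response genes, which cells transcribe when interferon receptors signal, were lower as a group in the E18.5 mutants. All 27 tested members had a negative log2 fold change (median -0.66, camera adjusted p 6.70e-32, with the estimated correlation 0.118). Of these, 1 fell when adjusted over all genes and 22 when adjusted over the list alone. Their mean log2 CPM differed by -0.68 ± 0.08 (SE) between genotypes, while macrophage and dendritic cell genes differed by -0.27 ± 0.39. Isg15, a ubiquitin-like interferon target, stood at 43.9 ± 8.30 and 19.6 ± 2.36 CPM (-1.17 ± 0.16, edgeR adjusted p 0.0552). The antiviral GTPase gene Mx1 stood at -1.20 ± 0.23 (0.172) and the interferon regulator Irf7 at -1.07 ± 0.20 (0.177). These 3 were chosen after their values were seen.

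Several groups of tissue-restricted genes were lower as well, although none by the estimated correlation. With that correlation 0 lists passed in any grouping of 6 libraries, even for adult against E18.5 wild-type, where 10464 genes changed. A miss by it among 6 libraries thus says little either way. With the same 6 E18.5 libraries regrouped regardless of genotype up to 14 lists passed camera, as many as with the real groups. Skeletal muscle genes had a median of -0.38 (camera adjusted p 3.49e-11, with the estimated correlation 0.182) with 0 of 25 fallen over all genes and 8 adjusted over the list alone (4 without wild-type 1 or without mutant 3). In this list muscle creatine kinase Ckm stood at -1.91 ± 0.30 (edgeR adjusted p 0.0992) and cardiac actin Actc1 at -0.58 (0.128). Keratinocyte genes had a median of -0.42 (3.47e-06, with the estimated correlation 0.179), 0 of 16 fallen over all genes and 1 adjusted over the list alone. The keratin Krt77 stood at -2.13 (edgeR adjusted p 0.128) and the surface protein gene Ly6d at -0.65 (0.894). Goblet and secretory cell genes had a median of -0.29 (0.000201, with the estimated correlation 0.211), 0 of 13 fallen over all genes and 1 adjusted over the list alone. Bpifb1, an airway secretory protein gene that is also near Insm1 (chromosome 2, 154190818 to 154220369), stood at -1.72 ± 0.27 (edgeR adjusted p 0.0992) and lactoferrin Ltf at -0.77 (-0.40 without wild-type 2). The goblet median was -0.20 without wild-type 1 and -0.51 without mutant 1. Of peptide hormone genes (median -0.30, 0.000536, with the estimated correlation 0.182), 0 of 9 fell over all genes and 2 adjusted over the list alone. Without 1 library their median ran from -0.86 (mutant 3) to -0.36 (wild-type 3), all below that of the full set. The filter was rerun each time, so the tested members may differ as well as the libraries. The calcitonin-related Calcb stood at -2.31 ± 0.32 (0.0612) and its paralog Calca, whose reads may not be fully separable, at -2.81 (0.332). Neuroendocrine genes, the closest targets to expect of Insm1, were negative in 17 of 21 (median -0.21, 0.000282, with the estimated correlation 0.149, and 0.0174 by fry against no change). Insm1 itself was the 1 member that fell by either adjustment, and the median was -0.12 without wild-type 3. With Insm1 taken out of the list, which was tried after the values were seen, the camera adjusted p was 0.00473 (with the estimated correlation 0.182, fry 0.0309).

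Further lists were called at E18.5 but lost the call without some single library. Enterocyte and hepatocyte genes (median -0.57, camera adjusted p 0.000924, with the estimated correlation 0.211) had 0 of 10 fallen over all genes and 1 adjusted over the list alone, and gave 0.0733 without mutant 2. Their median was -0.32 without wild-type 1. The mucin Muc13 stood at -2.53 and the keratin Krt20 at -2.44 (-4.79 without mutant 3). Epithelial genes (-0.13, 0.00104, with the estimated correlation 0.325), with 0 of 16 by either adjustment and the keratin Krt19 at -0.62, gave 0.0687 without wild-type 1 (median -0.063). Antigens commonly cited as Aire-dependent (-0.48, 0.0268, with the estimated correlation 0.453), with 0 of 8 over all genes and 1 adjusted over the list alone, gave 0.195 without wild-type 1, 0.107 without wild-type 2, 0.0967 without mutant 2 and 0.0681 without mutant 3. Casein beta Csn2, one of them, stood at -3.00 ± 0.46 (edgeR adjusted p 0.0992). Ionocyte genes (-0.22, 0.0262, with the estimated correlation 0.453), 0 of 8 by either adjustment and the ionocyte regulator Foxi1 at -0.98, gave 0.170 without wild-type 1, 0.0954 without wild-type 2, 0.738 without mutant 2 and 0.0681 without mutant 3. The ionocyte median ran from -0.51 without mutant 1 to -0.047 without mutant 2.

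Lists of mTEC maturity, of macrophages and of the cell cycle were called at E18.5 too, but without a stable call. Mature mTEC genes had a median of -0.08 (camera adjusted p 0.0221, with the estimated correlation 0.453; 0.898 without wild-type 3, where the median turned to 0.027, and 0.0967 without mutant 2), with 0 of 24 fallen over all genes and 2 adjusted over the list alone. Tnfrsf11b, the decoy receptor osteoprotegerin, stood at -1.64. Immature mTEC genes had a median of -0.03 (0.0331, with the estimated correlation 0.401; 0.195 without wild-type 1, 0.0902 without wild-type 3, 0.239 without mutant 2), with 0 of 19 by either adjustment. Their median was -0.11 without wild-type 2. The claudins Cldn3 and Cldn4 stood at -0.59 and -0.51. Macrophage and dendritic cell genes had a median of -0.19 (0.0267, with the estimated correlation 0.564; 0.0671 without wild-type 1, 0.437 without wild-type 2, 0.227 without mutant 2, 0.466 without mutant 3), with 0 of 18 over all genes and 2 adjusted over the list alone. Their direction was not stable, as the median turned to 0.15 without wild-type 2, 0.043 without mutant 2 and 0.025 without mutant 3, and was -0.58 without mutant 1. The phagocyte receptor Sirpa stood at -0.42 and the perforin-like Mpeg1 at -0.77. Cell cycle genes had a median of 0.10 (0.0221, with the estimated correlation 0.846; 0.195 without wild-type 1, and a median of -0.07 without mutant 1), with 0 of 27 by either adjustment. The mitotic kinase Aurkb stood at 0.18 and the replication helicase Mcm3 at 0.24 (0.076 and 0.048 without mutant 1). Not called were tuft (0.366), ciliated (0.897), microfold (0.296), cTEC (0.773), Aire-independent antigens (0.199, with C-reactive protein Crp at 0.53), thymocyte (0.428), B cell (0.0890), fibroblast (0.927), endothelial (0.428), erythroid (0.897), parathyroid and thyroid (0.929) and dissociation stress genes (0.442). In the microfold and ciliated lists the median and the mean differed in sign. Pancreatic acinar and adipocyte lists had fewer than 5 tested members at E18.5.

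**Figure D2:**
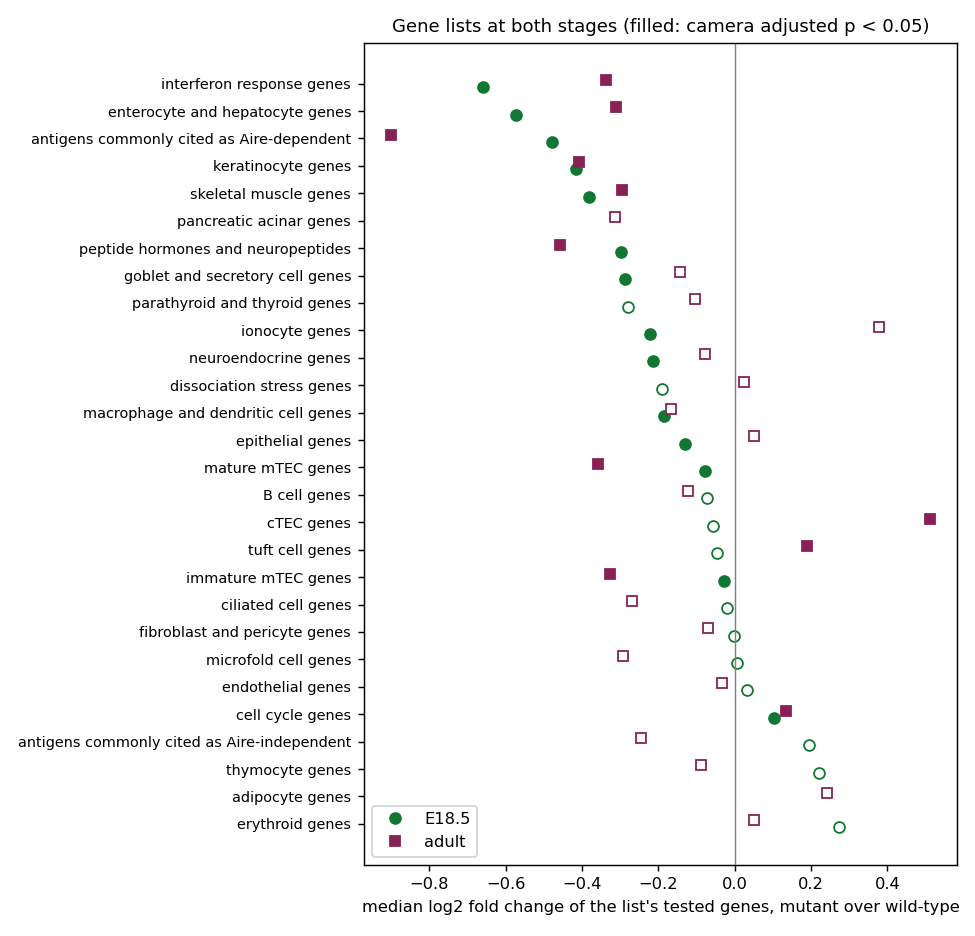
Median log2 fold change (mutant over wild-type, x axis) of each gene list at E18.5 and in adults, filled where the camera adjusted p was below 0.05. Interferon response genes stood at -0.66 at E18.5, and cTEC genes stood at 0.51 in adults.

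In adult mutants cTEC genes were higher and mTEC genes lower as groups by camera, without a single gene past the threshold in edgeR. With the estimated correlation neither held (adjusted p 0.607 for each), and fry, which tests against no change, called no adult list. cTEC line the thymic cortex, where they select thymocytes by their peptides, and share a progenitor with mTEC. Insm1 stood at 20.3 ± 7.56 CPM in wild-type and 4.85 ± 1.32 CPM in mutant mTEC (log2 fold change -2.06 ± 0.32 SE, edgeR p 0.000219, adjusted p 0.593). Aire stood at 99.3 ± 23.6 and 37.0 ± 7.59 CPM (-1.43 ± 0.21, p 0.000172, adjusted p 0.593). Fezf2 stood at 98.1 ± 2.76 and 63.2 ± 21.3 CPM (-0.63 ± 0.23, adjusted p 0.769), with mutant 3 the lowest at 38.6 unscaled CPM and a log2 fold change of -0.39 without it. The test was edgeR on 15348 genes with 0 called and 988 at an unadjusted p below 0.05 (767 by chance; 541 of them lower in mutants). DESeq2 called 74 (25 higher, 49 lower), with Insm1 and Aire both at an adjusted p of 5.34e-06. Voom and the FPKM fits called 0, and 1 fit of all 12 libraries called 3, among them Aire (0.0350).

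Of 19 cTEC genes 17 were positive in the adult comparison (median 0.51, camera adjusted p 1.82e-05, with the estimated correlation 0.607), with 0 risen over all genes and 8 when adjusted over the list alone. The thymus-specific serine protease gene Prss16 stood at 596 ± 159 and 1748 ± 914 CPM (1.55 ± 0.41, edgeR adjusted p 0.721), and the aminopeptidase gene Enpep at 39.3 ± 6.33 and 77.8 ± 21.7 CPM (0.98 ± 0.21, 0.721). The simple keratins Krt18 and Krt8, listed both as cTEC and as epithelial genes, stood at 0.74 and 0.57. The 8 became 0 without wild-type 1, wild-type 2, mutant 1 or mutant 3, 4 without wild-type 3 and 11 without mutant 2. Mean log2 CPM of cTEC genes differed by 0.52 ± 0.28 (SE), beside -0.06 ± 0.11 for thymocyte and -0.16 ± 0.20 for macrophage and dendritic genes. The differences were -0.18 ± 0.42 for B cell, 0.02 ± 0.25 for fibroblast and -0.08 ± 0.28 for endothelial genes. Within same-number pairs, compared after the values were seen, cTEC genes differed by 0.57, 0.29 and 0.71. The paired SE was 0.123 (paired t test p 0.0512, exact sign-flip p 0.25).

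Mature mTEC genes were negative in 23 of 25 in adults (median -0.36, camera adjusted p 2.08e-05, with the estimated correlation 0.607), with 0 fallen over all genes and 1 adjusted over the list alone. The size rested largely on wild-type 1, as the median was -0.078 without it (highest camera adjusted p without a library 0.0245) and -0.53 without mutant 1. Immature mTEC genes had a median of -0.33 (camera adjusted p 0.00356, with the estimated correlation 0.607; 0 of 19 by either adjustment, integrin Itga6 at -0.37 and keratin Krt17 at -0.57), and -0.20 without mutant 3. Interferon response genes were negative in 26 of 27 (-0.34, 7.50e-08, with the estimated correlation 0.607, 0 by either adjustment), with the T cell chemokine Cxcl9 at -0.96 ± 0.27 and the antiviral Oasl1 at -0.64. Peptide hormone genes had a median of -0.46 (0.00182, with the estimated correlation 0.607, 0 of 13 by either adjustment), with Calcb at -1.66 and proenkephalin Penk at 0.79 (0.42 without mutant 3). Without 1 library the hormone median ran from -0.87 (mutant 2) to -0.19 (wild-type 2), with a camera adjusted p of up to 0.0465. Skeletal muscle genes had a median of -0.30 (0.00220, with the estimated correlation 0.607, 0 of 19 over all genes and 2 adjusted over the list alone), with the myosins Myh1 at -1.58 and Myh8 at -1.65. The muscle median ran from -0.56 without wild-type 3 to -0.19 without wild-type 2. Regrouping the 6 adult libraries regardless of genotype gave up to 14 called lists against the real 11.

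Other adult lists lost their call without a single library. Keratinocyte genes (median -0.41, camera adjusted p 0.00103, 0 of 22 over all genes and 1 adjusted over the list alone, with the estimated correlation 0.723) gave 0.107 without wild-type 1 and 0.191 without mutant 3, with medians from -0.93 (without mutant 2) to -0.18 (without mutant 3). Krt77 stood at -1.27 ± 0.25 and Krt10, a keratin of upper epidermis, at -0.54. Cell cycle genes (0.14, 0.000948, with the estimated correlation 0.718, 0 of 27 by either adjustment) gave 0.193 without mutant 3 (median 0.032), with the checkpoint kinase Bub1b at 0.55 and the sliding clamp Pcna at 0.31. Tuft cell genes, of chemosensory mTEC, had a median of 0.19 (0.0442, with the estimated correlation 0.824, 0 of 26 by either adjustment) that became -0.09 without wild-type 3 (0.312) and gave 0.360 without mutant 1 and 0.161 without mutant 2. Neurogranin Nrgn stood at 0.28 and the cyclooxygenase Ptgs1 at 0.29 (0.088 without wild-type 3). Antigens commonly cited as Aire-dependent (-0.90, 0.0451, with the estimated correlation 0.607, 0 of 9 by either adjustment) gave 0.0925 without wild-type 1, 0.0729 without wild-type 2, 0.0589 without mutant 1, 0.0814 without mutant 2 and 0.301 without mutant 3. The median of these antigens was -0.24 without wild-type 1. Csn2 stood at -1.47, and at -0.70 without wild-type 2. Thyroglobulin Tg, also in that list, stood at -3.98 ± 1.54 only because of wild-type 1, and at -0.04 without it. Enterocyte and hepatocyte genes (-0.31, 0.0457, with the estimated correlation 0.723, 0 of 18 by either adjustment, apolipoprotein Apob at -1.73) gave 0.965 without wild-type 2, where the median turned to 0.047, 0.101 without mutant 1, 0.0844 without mutant 2 and 0.123 without mutant 3.

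Not called in adults by camera were neuroendocrine (adjusted p 0.119, granin-like Scg5 at -0.88), microfold (0.141), goblet (0.983), pancreatic acinar (0.191), ciliated (0.119), ionocyte (0.119, proton pump subunit Atp6v1b1 at 0.82), Aire-independent antigens (0.159, Crp at -1.52 ± 0.29) and epithelial genes (0.568). Of lists of other cells and states none of these was called: thymocyte (0.248), macrophage and dendritic (0.209, the lectin Cd209a at -1.01), B cell (0.216), endothelial (0.396), erythroid (0.851), parathyroid and thyroid (0.342), adipocyte (0.667) and dissociation stress genes (0.119). In the fibroblast list (0.983) the platelet-derived growth factor receptor Pdgfra stood at 1.03 ± 0.18 and the proteoglycan Lum at 1.09 (0 of 18 changed over all genes, 2 risen and 1 fallen adjusted over the list alone), while the median was negative and the mean positive, and the median and the mean or test also differed in sign for adipocyte and erythroid genes. The B cell receptor for IgE, Fcer2a, stood at 19.4 ± 4.50 and 8.74 ± 0.295 CPM (-1.15 ± 0.19, edgeR adjusted p 0.593).

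**Figure D3:**
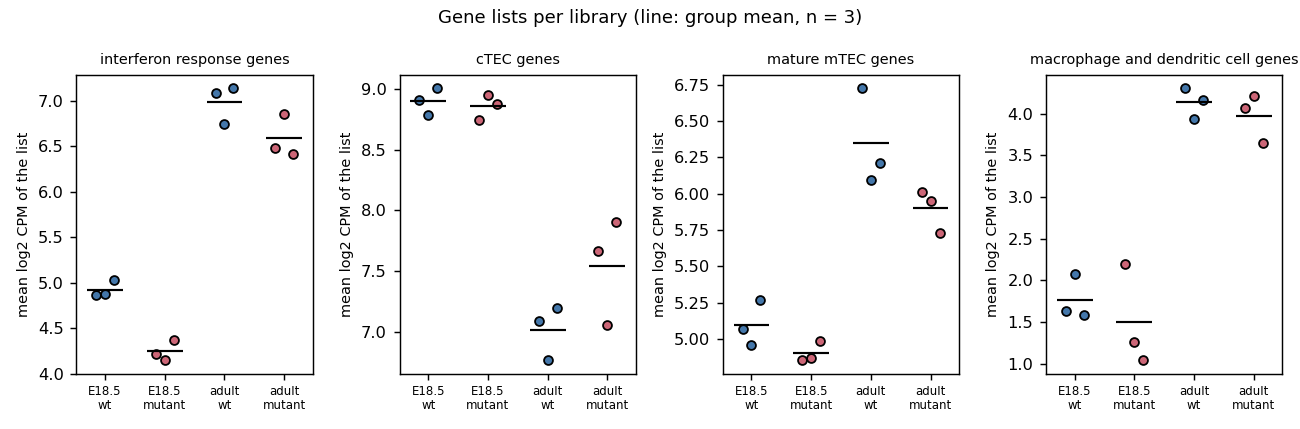
Mean log2 CPM of gene lists in each library (points) by genotype and stage. Interferon response genes separate the genotypes at E18.5 (difference -0.68), and adult cTEC genes differ by 0.52.

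Whether the genotype effect differed between stages was tested as an interaction, adult effect minus E18.5 effect. Insm1 gave 1.16 ± 0.44 (SE; edgeR adjusted p 0.930), Aire -0.60 ± 0.26 (0.961) and Fezf2 -0.16 ± 0.31 (1.0). Slc24a3, which rose at E18.5, stood at 0.05 ± 0.23 in adults (interaction -1.37 ± 0.29, edgeR unadjusted p 0.000363, adjusted p 0.805). Rin2 stood at 0.20 ± 0.14 (-0.69 ± 0.18, p 0.00215, 0.805), so a difference between stages was not shown for either. The adult Rin2 value ran from 0.12 without wild-type 2 to 0.36 without wild-type 3. edgeR called 0 of 15908 genes, 790 had an unadjusted p below 0.05 against 795 by chance. DESeq2 called 10, and without adult mutant 2 edgeR called 24. By camera cTEC genes (median 0.55, adjusted p 6.89e-06, 0 of 19 over all genes and 8 adjusted over the list alone), interferon response genes (0.27, 0.0105, 0 of 27 by either adjustment) and ionocyte genes (0.52, 0.0283, 0 of 11 by either adjustment) were more positive in adults, each with 0.978 by the estimated correlation and none by fry. The 8 cTEC genes became 0 without any library but E18.5 wild-type 2, E18.5 mutant 2, adult wild-type 3 or adult mutant 2 (9, 8, 9 and 12). The interferon call was lost without E18.5 wild-type 3 (0.0717, median 0.14), E18.5 mutant 2 (0.0573, 0.24), adult wild-type 2 (0.349, 0.13) or adult mutant 2 (0.342, 0.050). The ionocyte call was lost without E18.5 wild-type 1 (0.154), wild-type 2 (0.142), mutant 2 (0.352) or mutant 3 (0.0705), or adult wild-type 3 (0.315), mutant 2 (0.149) or mutant 3 (0.102), and its median ran from 0.26 without E18.5 mutant 2 to 0.82 without E18.5 mutant 1.

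**Figure D4:**
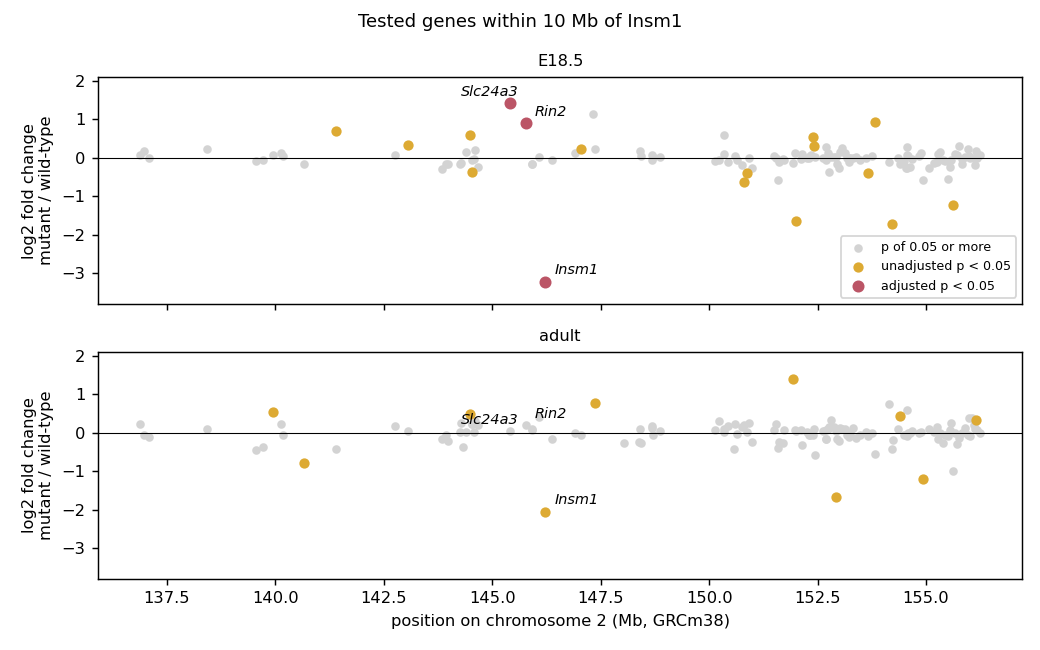
Log2 fold change (mutant over wild-type) of tested genes by position around Insm1 on chromosome 2 (GRCm38) at E18.5 and in adults. Slc24a3 (1.42) and Rin2 (0.90) stand out beside Insm1 (-3.22) at E18.5 and not in adults (0.05 and 0.20).

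Across 14043 genes tested at both stages the genotype effects correlated weakly (Pearson r 0.160, Spearman 0.0753, and 0.0534 by Pearson for 10116 genes with an average log2 CPM of 3 or more). Genes with an unadjusted edgeR p below 0.05 and lower at both stages numbered 61, where 12.8 were expected of independent stages, while 2 were higher at both (3.54 expected) and 21 went opposite ways. Among the 61 were Insm1, Aire, Fezf2, the epidermal Krt77, the hormone gene Calcb, the milk protein gene Csn2, and the interferon targets Oasl1 and Cxcl9.

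Wild-type mTEC of the adult differed widely from those of E18.5, a contrast that carries collection, pooling and sex makeup with it. Fezf2 rose from 17.9 ± 3.36 to 95.9 ± 2.41 CPM (log2 fold change 2.41 ± 0.14 SE, edgeR adjusted p 1.04e-06), while Aire (-0.04 ± 0.17, 0.845) and Insm1 (0.37 ± 0.28, 0.266) did not pass. Insm1 gave 0.037 without adult wild-type 1 and 0.63 without E18.5 wild-type 1, and Aire -0.22 to 0.13 without 1 library. The B cell genes Jchain, the joining chain of polymeric antibody, and Ms4a1, the surface antigen CD20, went from 9 to 224890 and from 3 to 2021 reads over 3 libraries. Ly6c2, a leukocyte surface gene, went from 3 to 5080 reads, of which 4645 lay in adult wild-type 1, and lost its call without any 1 of the E18.5 libraries (edgeR adjusted p 0.103, 0.0645 and 0.0978 without wild-type 1, 2 and 3). The antitrypsin paralogs Serpina1b and Serpina1a, whose reads may not be separable, went from 0 to 1807 and 840 reads, at least 682-fold and 317-fold with a floor of 3 reads. In the other direction the X-linked homeobox gene Rhox4b and the imprinted Zim1 went from 315 and 202 reads to 0, at least 92.8-fold and 59.5-fold. The cartilage gene Cnmd fell by 8.02 on the log2 scale (13617 to 51 reads), uromodulin-like Umodl1 by 8.72 (3013 to 6). The zinc-finger gene Zfp648 fell too (-8.07, 1855 to 6 reads). In all 5286 genes rose and 5178 fell of 15373.

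Many lists of other cell types rose between the stages in wild-type mTEC, and how far the contrast reflects the makeup of the preparations was not tested. By camera, B cell genes rose (13 of 13 members, median 6.11, adjusted p 1.52e-06), as did macrophage and dendritic (22 of 23, 2.96, 1.86e-07), endothelial (15 of 15, 3.68, 3.42e-07), tuft (24 of 25, 3.35, 1.98e-07) and interferon response genes (24 of 27, 1.99, 3.42e-07). Also higher were thymocyte (22 of 27, 1.13), fibroblast (13 of 18, 1.13), adipocyte (6 of 7, 3.29), keratinocyte (20 of 21, 2.60), microfold (11 of 14, 2.19), enterocyte and hepatocyte (13 of 18, 2.35), dissociation stress (16 of 21, 1.37) and mature mTEC genes (14 of 25, 0.75). cTEC genes (16 of 19 fell, -2.25, 2.69e-05), cell cycle genes (27 of 27, -2.06, 9.60e-11) and skeletal muscle genes (17 of 25, -2.12, 0.000202) were lower. With the estimated correlation the smallest adjusted p was 0.393, while fry, which tests against no change, called 23 lists.

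A loss of tissue-restricted transcripts could show as fewer genes detected. With E18.5 libraries thinned to 13124371 reads, 17764 ± 118 genes had a read in wild-type and 17289 ± 33 in mutant mTEC, a difference of -475 (exact permutation p 0.1, the smallest that 3 against 3 can give). With at least 5 reads asked of a gene the difference was -212 (exact permutation p 0.1). In adults, thinned to 13694330 reads, the counts were 18417 ± 355 and 18116 ± 38, a difference of -301 (exact permutation p 0.2) that was -100 without wild-type 2, and with at least 5 reads it was -257 (exact permutation p 0.1).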

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

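The tests of explanations and of regrouped libraries in these paragraphs were all chosen after the results were seen, and the labels of the macrophage and mTEC-share tests were tightened after first values were seen. Ionocyte genes had an interaction camera adjusted p of 0.0283, where no difference between stages had been foreseen. The call was lost without E18.5 wild-type 1 (0.154), wild-type 2 (0.142), mutant 2 (0.352) or mutant 3 (0.0705), and without adult wild-type 3 (0.315), mutant 2 (0.149) or mutant 3 (0.102). cTEC genes had an interaction adjusted p of 6.89e-06 and kept it below 0.05 without any 1 library, and interferon response genes had 0.0105, lost without E18.5 wild-type 3 (0.0717), E18.5 mutant 2 (0.0573), adult wild-type 2 (0.349) or adult mutant 2 (0.342). All 3 lists stood at 0.978 with the estimated correlation. Of 100 regroupings of the libraries within stages 94 called as many lists as the real 3, and up to 21, several times the real count. Such counts may come from structure of the samples, a preset correlation below the real one or the genotype effect itself, which were not tested apart. Some regroupings reversed the adult groups, so that an effect shared by both stages counted as a difference between them. The grouping with 21 lists kept the real E18.5 groups and put adult wild-type 3, mutant 1 and mutant 3 together. The regroupings are thus not free of genotype. With the estimated correlation the other groupings called at most 1 list.

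The genes that rose at E18.5 lie beside Insm1, and DNA of another origin carried along with the mutant allele was weighed as a cause. Within 10 Mb of Insm1, without Insm1, Slc24a3 and Rin2, 14 of 133 genes (10.5%) had an unadjusted p below 0.05 against 525 of 14361 (3.66%) elsewhere (exact Fisher p 0.000430, one-sided, with neighbouring genes treated as independent although they may not be). On the rest of chromosome 2 the share was 5.18% of 984 genes, a comparison that was not tested. Linked DNA carried at both stages would leave a raised share near Insm1 in adults as well. There the shares within 10 Mb and elsewhere were 6.57% and 6.43% (exact Fisher p 0.523). The labels do not say whether the mutants of both stages carry the same allele, so the adult shares cannot decide the question for E18.5. The rest of chromosome 2 stood at 7.08% of 1059 genes in adults. Whether the mutation acts alike at both stages cannot be told either. The mean interaction of Slc24a3 and Rin2 was -1.03, but both were picked for their E18.5 change and neither interaction passed adjustment. Dzank1, chosen after its value was seen and also near Insm1 (chromosome 2, 144470557 to 144527414), was 1 of the 2 genes with p below 0.05 and higher at both stages (0.60 and 0.49).

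The higher cTEC genes of adult mutants were not the work of 1 mutant library, as the lowest median without one was 0.396. Relative to 5 other cell types cTEC genes differed by 0.615 ± 0.314 (SE), which cannot tell a gain of cTEC transcripts from a lower share of mTEC. Within same-number pairs, a comparison also added after the results were seen, the differences were 0.80, 0.19 and 0.84 (paired SE 0.210, paired t test p 0.0998, exact sign-flip p 0.25). All 3 differences were positive, but the sign-flip p was the smallest that 3 pairs can give. The measure bears only on a lower share of mTEC that raises all other cell types alike. Fewer mTEC with more cTEC in the preparation would also give positive differences, so the question stays open. Of the 4 adult regroupings that part all 3 same-number pairs, the real one called 11 lists and the others 7, 11 and 6.

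The lower interferon response genes of E18.5 mutants were not due to 1 library alone (median closest to 0 without a library, -0.553) or the sex makeup of the pools (-0.666 with the share of Y-linked reads as covariate). Fewer macrophages and dendritic cells could not be told apart from a change in mTEC, since their genes less the interferon genes differed by 0.412 ± 0.428 (SE).

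Regrouped libraries were also compared with the real groups for each count. At E18.5 the real groups gave 5 changed genes, reached by 1 of 10 splits, the real one (highest other 1), and 14 lists, reached by 2 (highest other 14). In adults they gave 0 genes, which all 10 reach by construction (highest other 1), and 11 lists, reached by 7 (highest other 14). Between stages in wild-type mTEC they gave 10464 genes, reached by 1 of 10 (highest other 0), and 16 lists, reached by 3 (highest other 19). For all of these the 10 splits are too few for a share under 0.05.

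For designs with 100 splits, a share under 0.05 reached the 7 genes over both stages (1 split, the real one, highest other 1). The same held for the 5 lists over both stages with an estimated correlation (1, highest other 1). With Insm1 taken out of the neuroendocrine list these were 4 lists. It also held for the correlation of the stages (0.160 reached by 2, highest other 0.174). The splits and the additive fit were chosen after the values were seen, and 1 of the 7 genes is Insm1. Chance is thus not excluded for these results. The 16 lists over both stages by camera with the preset correlation were reached by 6 (highest other 19), which is above that share. The 0 interaction genes are reached by all 100 by construction (highest other 1), so the splits say nothing about them. Preset-correlation camera called a median of 11 lists in the other adult groupings, as many as the real 11. At E18.5 and over both stages the medians were 8 and 8, below the real 14 and 16. Other groupings reached those counts, so the number of such calls is weak evidence on its own. As those groupings could keep part of a genotype effect, they do not give the number of calls without one.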

How the results depend on the processing

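Some counts depended on the tool, and the cause was not tested. At E18.5 the 5 changed genes were 27 without a filter, 54 by DESeq2, 30 by voom, 3 with an absolute log2 fold change of 1 or more, 0 on log2(FPKM + 1) of all genes, 2 with the share of Y-linked reads as covariate (male share covariate, added after the values were seen) and 1 to 9 with 1 library left out. With replicate number as a block they were 16, but the numbers do not pair the E18.5 samples: same-number correlations were -0.074, 0.135 and 0.161, and wild-type 1 correlated best with mutant 3 (0.178). In adults the 0 genes were 74 by DESeq2 and 3 in 1 fit of all 12 libraries. The interaction's 0 genes were 10 by DESeq2 and 0 to 24 without a library, and the 10464 stage genes 9469 to 10599. The 7 genes over both stages (fit added after the values were seen) were 98 by DESeq2 and 1 to 11 without a library.

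With the estimated correlation camera called 0 lists at E18.5 (14 with the preset), 0 in adults (11), 0 for the interaction (3), 5 over both stages (16) and 0 for stage (16). By fry, which tests a list against no change and not against other genes, 2, 0, 0 and 7 were called in the first 4 of these. Without a library the list counts were 9 to 18, 11 to 13, 1 to 11, 14 to 18 and 15 to 17 in that order. A block, run only for the comparisons within a stage, gave 12 lists at E18.5 and 12 in adults.

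The correlation of the stages (0.160) was 0.0534 for genes with an average log2 CPM of 3 or more, and 0.0930 to 0.179 without a library. The difference in detected genes was -212 at E18.5 and -257 in adults with at least 5 reads, and -542 to -429 at E18.5 and -438 to -100 in adults without a library.

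Of 1517 values of 92 gene results, 1510 kept their direction. Reversals were Slc24a3 in adults (-0.09, -0.06 and -0.10, range -0.10 to 0.26 without a library), the Fezf2 interaction (0.078, range -0.36 to 0.078) and Aire between stages (0.018 with total counts, 0.05 and 0.13, range -0.22 to 0.13). Of 239 values of 25 lists 195 were the same and 36 weaker, and 8 had a reversed direction or median: cell cycle genes at E18.5 (-0.068, range -0.068 to 0.26, and -0.043 with the male share covariate), macrophage and dendritic cell genes at E18.5 (0.15, 0.043 and 0.025, range -0.58 to 0.15), mature mTEC genes at E18.5 (0.027, range -0.15 to 0.027), adult enterocyte and hepatocyte genes (0.047, range -0.62 to 0.047) and adult tuft cell genes (-0.090, range -0.090 to 0.40).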

Other observations

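Aire was lower in Insm1 mutants over the 2 stages, along with a few single genes. In an additive fit of all 12 libraries, added after the values were seen, Insm1 fell (log2 fold change -2.57 ± 0.27 SE, edgeR adjusted p 0.00324), as did Aire (-1.12 ± 0.15, 0.0303), the neuropeptide gene Calcb (-1.92 ± 0.29, 0.0381) and the epidermal keratin Krt77 (-1.58 ± 0.23, 0.0381). The IgE receptor gene Fcer2a (-1.17 ± 0.18, 0.0382) fell too, and so did inducible nitric oxide synthase Nos2 (-1.20 ± 0.18, 0.0381) and the phospholipase Pla2g5 (-3.19 ± 0.49, 0.0382), the last 2 chosen after their values were seen. Fezf2 stood at -0.56 ± 0.15 (0.385). The planned fits gave 5 genes at E18.5 and 0 in adults, and in the additive fit only Insm1 passed without any 1 of the libraries (adjusted p up to 0.0235). Aire lost its call without E18.5 wild-type 2 (0.0936), E18.5 mutant 1 (0.0596), E18.5 mutant 2 (0.0874) or adult mutant 1 (0.120), and without the worst library of each the other 5 stood at 0.120 (Calcb and Krt77), 0.140 (Fcer2a and Nos2) and 0.172 (Pla2g5).

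Over both stages 5 lists were lower by camera with the estimated correlation as well, 1 of them only with Insm1 counted in it. That was the neuroendocrine list (median -0.16, 24 of 28 negative, adjusted p 0.0236), which without Insm1 had 23 of 27 negative, a median of -0.15 and an adjusted p of 0.0524 (0.00354 at the preset correlation, 0.0434 by fry). With Insm1 counted, the median ran from -0.25 (without adult mutant 3) to -0.12 (without E18.5 wild-type 3). Taking Insm1 out barely moved the size and the p just missed the threshold, so a loss of neuroendocrine genes beyond Insm1 stays open. The other lists were peptide hormones and neuropeptides (-0.69, 0.0236), skeletal muscle genes (-0.50, 0.0236), antigens commonly cited as Aire-dependent (-0.70, 0.0236) and interferon response genes (-0.43, 0.0256). Of the interferon genes 23 of 27 fell when adjusted over the list alone and 0 over all genes. Without 1 library the hormone median ran from -1.09 (adult mutant 2) to -0.60 (adult wild-type 2). The interferon list lost its call without E18.5 wild-type 1 (0.0526), wild-type 2 (0.0587), wild-type 3 (0.0652), mutant 1 (0.0645) or mutant 2 (0.0633), or adult wild-type 3 (0.0525) or mutant 1 (0.0670), while the other lists kept 0.0495 or less. No more than 1 list was called this way in any other of 100 regroupings. Whether lower Aire, a direct action of Insm1 or a lower share of mTEC lay behind the tissue-restricted lists among these 5 was not tested. The data cannot tell them apart.

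The E18.5 pools differed in makeup. Xist stood at 824, 1036 and 1.2 unscaled CPM in wild-type and 0.844, 777 and 323 in mutant replicates, and Y-linked genes at 43.4, 117 and 197 against 246, 122 and 160, so the sex makeup of the pools differed. Wild-type 3 and mutant 1 had hardly any Xist, while the other 4 pools had both Xist and Y-linked reads. All adult libraries had Xist and 0 Y-linked reads, so sex makeup also differed between the stages. It cannot be separated from stage in the stage and interaction comparisons. Thymocyte genes had a mean log2 CPM of 4.19, 5.47 and 5.01 in wild-type and 5.85, 4.60 and 4.45 in mutant pools at E18.5. Among the adult libraries mutant 3 had the lowest mean of mature mTEC genes (5.73) and the lowest Fezf2. Residual Insm1 reads in mutants were not traced to exons, since only gene totals were deposited.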
